A study of Mus musculus with 18 samples.

How the data were processed

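Tail DNA of 9 C57BL/6 mice of 1 family, namely 1 father, 1 mother and 7 progeny, was measured by array comparative genomic hybridisation. In this assay the DNA of a mouse and that of a reference are labelled with different dyes and compete for the same probes, so that the ratio of both signals follows the relative copy number. Each mouse was hybridised against the DNA of 1 male mouse of the same colony on 2 arrays with the dyes exchanged, which makes 18 arrays. The arrays of a mouse were counted as 1 replicate, and p-values over mice leave out the spread of the reference. The groups, the father, mother and progeny, were taken from the labels.

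The deposited scanner files hold, per spot, the red and green signals as intensity, background-subtracted and normalised between the dyes with a linear factor by Agilent Feature Extraction, per the file headers. They also hold the log10 ratio of red over green, which Feature Extraction computed from those signals, per the file headers. The authors' deposited value table holds log2 ratios of the reference over the mouse. Its direction was found by setting each column against the log2 ratio of the same array, and its column medians lay between -0.0264 and 0.0154. Whether it was scaled further is not given in the sources used here. For 16 of the arrays the table followed the scanner file (r of -0.9824 or stronger), while the father's columns had r of -0.2356 and -0.233 and so did not follow the father's scanner files. Which hybridisations these columns come from is not given in the sources used here. DNA extraction and labelling followed a tissue extraction protocol and Agilent's oligonucleotide array protocol, per the labels.

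Each array held 966371 non-control spots for 950713 distinct probes placed on mm9, of which 950622 were autosomal, 68 on X and 23 on Y. Another 36 spots on unplaced sequence were left out. The median spacing of autosomal probes was 2053 bp. Between 103 and 272 spots per array were marked as outliers in the files and left out, and no spot was saturated. Median net green signal ran from 51.7 to 182 and between 1354 and 27121 spots per array were not well above background. The father's and mother's arrays were scanned on a G2600D scanner with 2 passes and extracted with version 12.1.0.3. The progeny's arrays were scanned on a G2505C scanner with 1 pass and extracted with version 10.7.1.1. There were 7 scan batches. The parents shared 1, progeny 6 and 7 shared another, and each of the other progeny had its own.

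From the processed signals the log2 ratio of mouse over reference was computed and centred on each array's autosomal median. Spots of 1 probe were averaged. The dye effect common to the mice, taken as the median over mice of 0.5 times the difference between orientations, was removed from each probe. Regions were called in each mouse as runs of consecutive probes with a score of at least 6, where the score is the summed log2 ratio over the robust SD times the square root of the number of probes. A region needed 3 or more probes, a mean of at least 0.25 in size, and at least 0.125 with the same sign in each orientation. Gaps above 1 Mb ended a run. Overlapping regions were joined into loci, and each locus was valued over its highest-scoring region. A mouse was taken as not different at a locus where its mean was under 0.125 in size. Noise was estimated by the same procedure after turning the sign of 1 orientation of each mouse.

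Windows of 10 consecutive probes, 95054 in all, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05 and a mean log2 of at least 0.25 in size). One fit set the 7 progeny against 0, and another set progeny against parents. Differences of single values used two-sided exact permutation tests, and shares used two-sided exact binomial tests with exact 95% intervals. Calling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.

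The procedures were tested on simulated data, made by adding shifts to the pairs with the sign of 1 orientation turned. Losses of -1 log2 were recovered in 100% of cases with 3 or more probes. Gains of 3 copies against 2 with 3 probes were recovered in 92.1% of cases in the progeny and 37.5% in the parents, and with 10 probes in 100% and 95% of cases. Under the stricter requirement described next, such gains with 10 probes were recovered in 100% of cases in the progeny and 57.5% in the parents. With 5 probes these shares were 83.6% and 5%. In the limma fits, added shifts of 0.3 in size were recovered in 100% of windows in the progeny alone, with 0 false calls. Removing the common dye effect centres each sign-turned probe on 0 across the mice. That fit sets the progeny against 0, so its lack of false calls was nearly fixed in advance and does not apply to the measured windows. Between progeny and parents, 80% of windows shifted by 0.3 and 74% of windows shifted by -0.3 were recovered, with 19 false calls among 95054 windows.

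The thresholds, tests and most alternatives were fixed before the data were examined. A stricter requirement was chosen afterwards: a score of at least 9, 5 or more probes, and a median probe of at least 0.25 in size in each orientation. It was picked after viewing called and sign-flipped counts under it and under 33 other settings, partly because it gave few sign-flipped regions, so its own sign-flipped count is not independent evidence. The closing section gives the called regions under each of them and sums up the sign-flipped ones. The loci named in the text are the 12 with the largest mean log2 in any mouse, up to 10 loci called in progeny and absent in the parents by score, and the 9 loci of the stricter requirement, which were therefore singled out after their values were seen.

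The files give positions on mm9 and no gene names, and the gene table used here is for another assembly, so positions were not assigned to genes. The tests of preset gene lists and the look-up of 4 preset loci were not run. The alternative with normexp background correction (offset 50) used median signals, as the files give no mean signals. Other alternatives were the value table, other scores, probe numbers and sizes, single orientations, spots marked as outliers kept, dim probes left out, a running median of 1001 probes subtracted, and the dye effect left in. All columns of the value table were matched to arrays.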

Results

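The data describe the genomes of 1 mouse family. Tail DNA of a father, a mother and their 7 progeny was set against DNA of 1 reference male from the same colony, on 2 dye-swapped arrays per mouse. The labels conflict on the father: the title concerns males exposed to continuous low-dose gamma rays, whereas the design text counts the male of this family as non-irradiated. No other family was analysed here, so no comparison tests radiation. The question that the design does pose is which copy number differences the progeny share with their parents and which they do not. Values are mean log2 ratios of mouse over reference, and positions are on mm9. The robust SD of single probes was 0.176 in the father, 0.252 in the mother and 0.099 to 0.15 in the progeny, and the number of arrays limits the precision.

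The family differed from the reference most clearly by a gain of 160.1 kb on chromosome 4 (101110482 to 101270535, 74 probes), which all 9 mice carried. The gain was 0.55 in the father and 0.91 in the mother. It was 0.56, 0.52 and 0.56 in progeny 1, 5 and 6, and 0.94, 0.94, 0.95 and 0.93 in progeny 2, 3, 4 and 7. For reference, 3 copies against 2 give a log2 ratio of 0.58 and 4 copies against 2 give 1. In the limma fit over the progeny, 7 windows inside this gain were higher than the reference in 7 of 7 mice, by 0.74 to 0.81 on average (largest adjusted p 5.23e-10).

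A loss of 821.4 kb on chromosome 14 (53430657 to 54252014, 82 probes) met the limit of 0.25 in both parents and 5 of the progeny. Progeny 3 and 6, at -0.24 and -0.21, lay below the reference but fell short of that limit. The locus was -0.49 in the father, -0.53 in the mother and -0.26 ± 0.027 (SD, n = 7) in the progeny, in which it ranged from -0.29 to -0.21. All values fell short of the -1 that 1 copy against 2 gives. The progeny lay above the parents by 0.26, more than the spread among the progeny (two-sided exact permutation test, p = 0.0278, the smallest that 36 splits can give). The bounds of the locus are those of the father's region, and it was singled out after its values were seen. In a window across its end (54223715 to 54323910) the father had -0.27, the mother -0.44 and the progeny -0.28 on average. In the limma fit over the progeny, 5 windows in and beside this loss were lower than the reference in 7 of 7 mice, by -0.38 to -0.28 (largest adjusted p 8.05e-09). The parents' arrays formed a scan batch of their own, and the father's columns of the deposited value table, which do not follow the father's scanner files, gave -0.26.

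Smaller loci separated members of the family. A loss of 12.3 kb on chromosome 19 (34628286 to 34640600, 6 probes) was -0.79 in the father and -0.95, -0.91, -1.0, -0.95 and -0.76 in progeny 2, 3, 4, 6 and 7. The mother and progeny 1 and 5 did not differ from the reference there, with values between -0.05 and -0.02. With normexp background correction the value of progeny 3 moved from -0.91 to -0.40. The loss was carried by 5 of 7 progeny (two-sided exact binomial test against equal shares, p = 0.453). It also gave the remaining window of the limma fit over the progeny, with a mean of -0.38 (adjusted p 0.00101; under -0.4 in 5 of 7 mice). A loss of 30.1 kb on chromosome 3 (25414118 to 25444229, 5 probes) was -0.82 in the mother, 0.08 in the father and -1.20, -1.17, -1.16 and -1.10 in progeny 4, 5, 6 and 7. The values of progeny 1, 2 and 3 there were -0.08, 0.05 and 0.02. This locus was carried by 4 of 7 progeny (exact binomial p = 1), and it overlaps the deepest of 17 losses, described further on, that these 4 progeny carried together. On X and Y these 4 progeny lay with the mother, also given further on, so the share does not by itself show segregation.

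**Figure D1:**
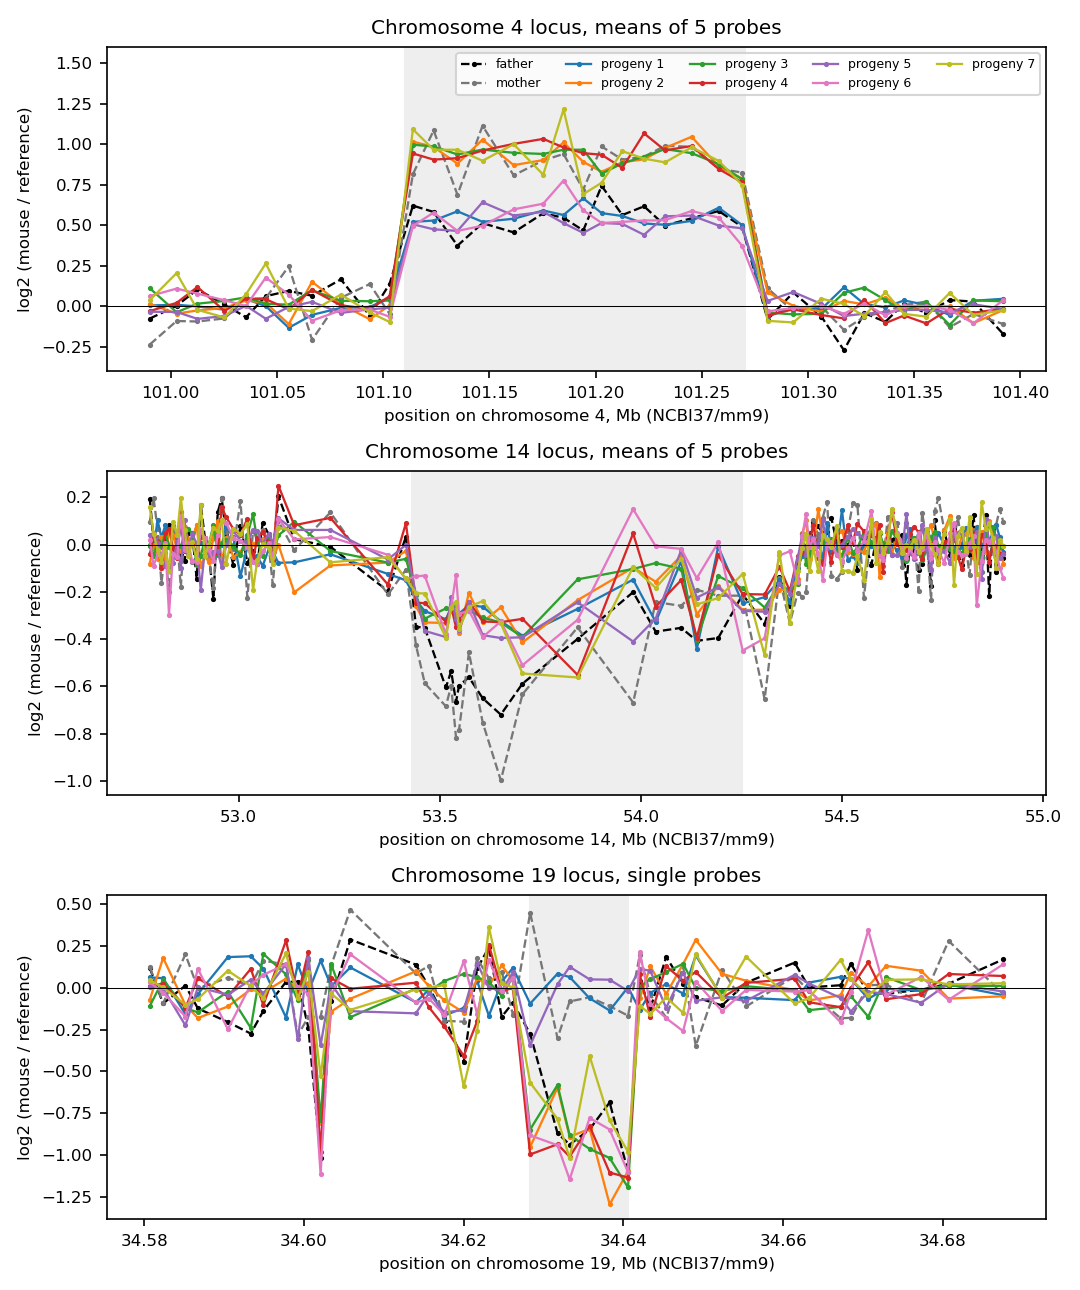
Log2 ratio of mouse over reference along 3 loci, against position in Mb on mm9, with 1 line per mouse (parents dashed) and the locus shaded. The chromosome 4 gain lies at 0.52 to 0.56 or at 0.91 to 0.95, the chromosome 14 loss is deeper in both parents (-0.49 and -0.53) than in the progeny, and the chromosome 19 loss is seen in the father and 5 of 7 progeny.

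These loci are among 9 that met a stricter requirement, which was chosen after the data had been seen. A gain of 128.2 kb on chromosome 8 (102125282 to 102253497, 46 probes) was 0.24 in the mother, 0.28, 0.30, 0.25 and 0.29 in progeny 4 to 7, and between 0.01 and 0.05 in the father and progeny 1 to 3. On chromosome 14, an 11-probe loss (61798066 to 61815412) was -0.23, -0.44, -0.22 and -0.19 in progeny 4 to 7 and -0.16 in the mother, and between -0.01 and 0.03 in the father and progeny 1 to 3. In progeny 5 it was -0.28 with normexp correction. A 5-probe locus of that chromosome (52007419 to 52020523) was -0.13 and -0.31 in the father and mother, and 0.17 to 0.61 in the progeny, but 0.17 in the father's columns of the value table. A 5-probe loss on chromosome 10 (39932202 to 39939362) was -0.47 in progeny 1, and a 5-probe gain on chromosome 4 (140359377 to 140366109) was 0.62 in progeny 6 and 0.22 in progeny 7. With normexp correction these fell under the limit of 0.25, to -0.14 in progeny 1 and 0.15 in progeny 6. With dim probes left out they kept it, at -0.265 and 0.3. Neither parent differed at the chromosome 10 locus or at this chromosome 4 gain.

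X and Y show how the arrays responded to a known difference in copy number, as the mother is labelled female and the reference male. The median of 68 X probes was 0.92 in the mother and -0.01 in the father, and the median of 23 Y probes was -2.20 in the mother and 0.04 in the father. Among the progeny, the X medians of mice 1 to 7 were -0.01, 0.01, -0.02, 0.99, 0.94, 0.89 and 0.92. Their Y medians were -0.06, 0.07, 0.00, -2.37, -2.12, -1.56 and -1.74. With normexp background correction the mother's X value shrank to 0.50 and the Y value to -0.29. As this correction shrank a known difference, a value under 0.25 with it does not by itself show a call to be false.

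Several short autosomal losses occurred together in progeny 4 to 7, whose X and Y medians lay with the mother's. At the planned threshold, 18 loci were carried by exactly 4 of the 7 progeny while the other 3 did not differ, and 17 of these were carried by progeny 4, 5, 6 and 7. All 17 were losses, spread over 11 chromosomes, and 16 of them had 3 probes. The mother carried 11 of the 17 and the father 1. The deepest lay on chromosome 3 (25417435 to 25444229, 4 probes), with -1.48, -1.51, -1.38 and -1.35 in these progeny, -1.06 in the mother and 0.09 in the father. Another, on chromosome 6 (104238274 to 104242812), was -0.93, -1.04, -1.25 and -1.09 in them, -0.61 in the mother and 0.03 in the father. These loci were looked at together only after their values had been seen.

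**Figure D2:**
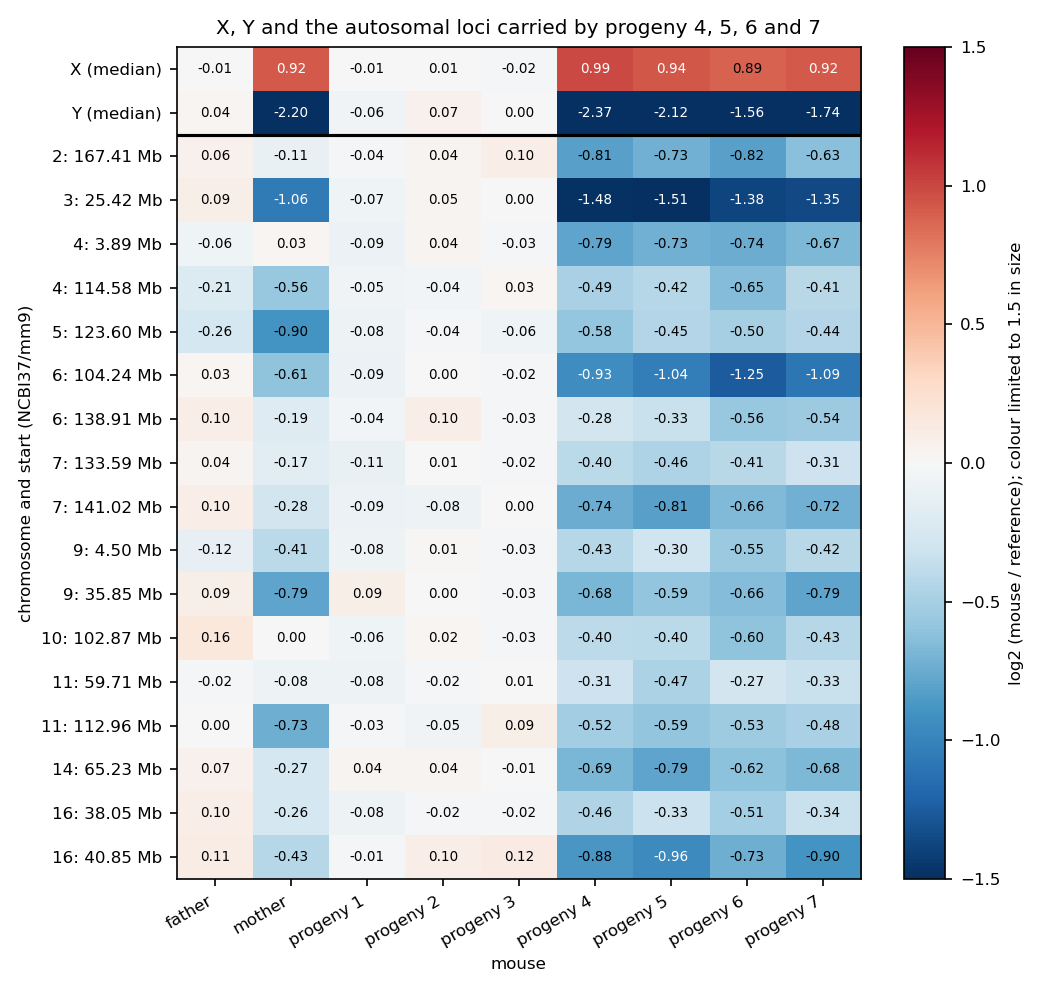
Log2 ratio of mouse over reference (printed and coloured) for each mouse at the X and Y probes (medians) and at the 17 autosomal losses carried by progeny 4, 5, 6 and 7, with chromosome and start on mm9. The mother carries 11 of these losses and the father 1.

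Across the autosomes, the planned threshold gave 1555 regions in the 9 mice, 750 gains and 805 losses, which formed 1380 loci. Most were short: 78.5% of the regions had 3 probes, and 1274 loci were called in 1 mouse, against 106 in 2 or more and 2 in all 9. The same procedure with the sign of 1 orientation turned gave 1976 regions and 1815 loci, so at this threshold the number of calls did not exceed this estimate of noise. Only the dye effect common to the mice had been removed. A dye effect of a single mouse would cancel in the called mean but stay in the sign-turned profile. The 1976 may therefore overstate noise, and they do not show how many of the 1555 regions are true. Regions of 10 or more probes were more frequent than in the sign-turned data, at 42 against 11. Calls did exceed the sign-turned count with normexp correction, at 313 regions against 122, and for a mean of at least 0.5, at 820 against 684. With the common dye effect left in there were 1448 regions against 565 sign-turned ones, which does not show calls above noise. The dye effect cancels in the mean of both orientations but stays in the sign-turned profile, so the 565 do not estimate noise alone. Under the stricter requirement, 33 regions stood against 1, forming the 9 loci above, but it was chosen partly for that low count.

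**Figure D3:**
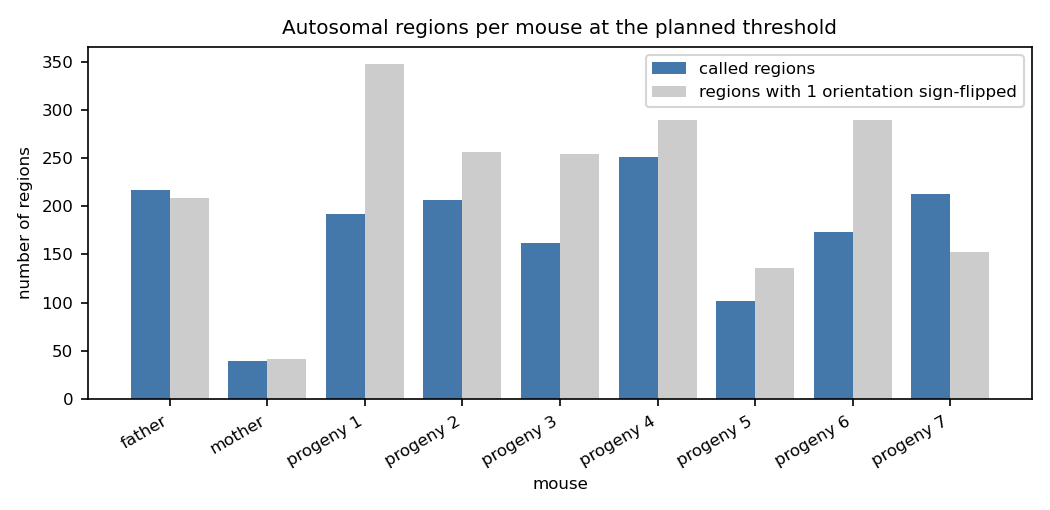
Number of autosomal regions per mouse at the planned threshold (dark bars) and after turning the sign of 1 orientation (light bars). The father has 217 regions, the mother 39 and the progeny between 102 and 251, and the sign-turned counts are higher in every mouse but the father and progeny 7.

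The 12 loci with the largest mean log2 in any mouse were mostly seen in single mice. They included the chromosome 3 and 6 losses given above and another loss on chromosome 3 (132549431 to 132553080), which was -1.05 in progeny 5, between -0.81 and -0.77 in progeny 4, 6 and 7, and -0.38 in the mother. Of the others, 3 were called in the father, at 1.06, -1.02 and 1.02 on chromosomes 1, 13 and 1, and all 3 had the opposite sign in the father's columns of the value table. A further 4 were called in the mother, at -1.29, -1.07, 1.05 and -1.04 on chromosomes 3, 12, 18 and 4, and with normexp correction these were -0.63, -0.44, 0.67 and -0.54. Progeny 7 had the remaining 2, on chromosomes 11 (55913468 to 55916508) and 14 (114019472 to 114023022), at -1.33 and -1.22. When the most extreme spot was left out, 6 of the 12 fell under 0.25 in size. At the latter 2 loci that spot read -7.27 and -6.74, and the means without it were -0.14 and -0.12.

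The design asks which changes of the progeny are absent in the parents. Progeny calls at loci where neither parent differed in the same direction numbered 744, fewer than the 1246 of the sign-turned data. The 1246 may overstate noise in the same way as the sign-turned regions above. Without the most extreme spot of each, 41.7% of the 744 progeny calls fell under 0.25, against 35.9% of all regions and 54.1% of all sign-turned ones. The comparison turned with normexp correction, at 93 calls against 76. It also turned with the common dye effect left in, at 689 against 124. There the sign-turned profiles hold the dye effect common to parents and progeny, so the 124 do not estimate noise alone. By score, the leading ones besides the progeny 7 calls on chromosomes 11 and 14 were short. On chromosome 14 (52008939 to 52012105) all 7 progeny were raised, with 0.31, 0.30, 0.75, 0.59, 0.48, 0.62 and 0.94 in mice 1 to 7, while the father had -0.20 and the mother -0.43, in the scan batch of their own. On chromosome 4 (140360794 to 140363810) progeny 6 had 0.99 and progeny 7 had 0.43, with the father at 0.05 and the mother at -0.03, but the value of progeny 6 was 0.19 with normexp correction and 0.53 with dim probes left out. Losses on chromosomes 2 (167410733 to 167414542) and 4 (3890510 to 3894138) were -0.81 and -0.79 in progeny 4 and were also carried by progeny 5, 6 and 7. Without the most extreme spot the progeny 4 means were -0.44 and -0.50. Both are among the 17 short losses that followed the X and Y medians of the progeny. The other 4 had 3 probes each and read -0.70 in progeny 2 on chromosome 13, -0.59 in progeny 3 on chromosome 2 (-0.40 in progeny 7), -0.62 in progeny 1 on chromosome 17 (-0.65 in progeny 6) and 0.75 in progeny 5 on chromosome 8. With normexp correction the first-named mouse at each had -0.057, 0.019, -0.066 and 0.54. With dim probes left out the same mice had -0.19, -0.01, -0.225 and 0.844. Normexp correction also shrank known differences, the mother's X to 0.50 and Y to -0.29. It left the X of progeny 4 and 5 at 0.77 and 0.79. A fall under 0.25 with that correction therefore does not by itself tell false from true. Only the chromosome 8 gain kept a size of 0.25 under both settings. That gain read 1.19 in 1 orientation and 0.31 in the other, and 0.26 without its most extreme spot. Under the stricter requirement 4 such calls stood against 0, at the chromosome 10 locus in progeny 1, the chromosome 4 gain in progeny 6 and the 5-probe chromosome 14 locus in progeny 3 and 7. The first 2 fell under 0.25 with normexp correction but not with dim probes left out. At the last the father's columns of the value table had the sign of the progeny.

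Few of the parental calls at the planned threshold were seen again in the progeny. Exactly 1 parent carried 262 loci, the father 182 and the mother 80, and the progeny carried them in 153 of 1834 cases, or 8.3% (exact 95% interval 7.1% to 9.7%). No progeny carried 155 of the 262 loci. The planned two-sided exact binomial test against equal shares gave p = 2.6e-325 but does not measure inheritance. Parental values made by noise are not inherited, and the number of such loci among the 262 is not known. Of the father's 217 regions, 8 reached 0.25 in the father's columns of the value table. Under the stricter requirement 2 loci remained, the chromosome 19 and chromosome 3 losses, and the share was 9 of 14, or 64.3% (exact 95% interval 35.1% to 87.2%, exact binomial p = 0.424). As the chromosome 3 locus is among losses that progeny 4 to 7 carried together, the share without it rests on 1 locus, with 5 of 7.

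The number of regions per mouse did not separate the generations. The progeny had 186 ± 46.9 regions (SD, n = 7), and the father and mother had 217 and 39. The progeny mean exceeded that of the parents by 57.6 (two-sided exact permutation test, p = 0.3056 over 36 splits). Without the mother the difference was -31.4, and for regions of at least 0.5 in size it was -35.9.

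Progeny and parents differed in 29 of 95054 windows in the limma fit, with 21 higher and 8 lower in the progeny. The fit assumes the same spread in all mice and takes it mostly from the progeny. The parents were noisier, with a robust SD of 0.176 and 0.252 against 0.099 to 0.15, so its p-values are likely too small. An unadjusted p under 0.05 was reached by 20692 windows. Of the 29 windows, 4 lay inside the chromosome 14 loss, at 0.30 to 0.42 (adjusted p 7.57e-05 to 0.000241), and the 7 progeny all lay above both parents there. Outside it, the largest differences were 0.33 on chromosome 7 (88363315 to 88376835; parents -0.28, progeny 0.05 ± 0.038, SD, n = 7; adjusted p 0.000919) and -0.33 on chromosome 16 (89809132 to 89829290; parents 0.32, progeny -0.01 ± 0.044, SD, n = 7; adjusted p 0.00077). The same fit gave 19 false calls in simulated data made from sign-turned pairs, 777 windows without the father, 100 without the mother and 44 without progeny 5. With the value table it gave 0 windows (15735 at an unadjusted p under 0.05), and the parents shared a scan batch that held no progeny, so batch and generation cannot be told apart.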

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

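The tests in this part were chosen after the results were seen. Among 33 quantities measured in the 7 progeny, 4 had 1 mouse whose distance from the others was above the critical share of the range. Chance gives about 1 in 20 for quantities picked without regard to their values, but all but 4 of the 33 were loci named for their size or score, among them all those above the critical share. That rate does not hold for them, and the test does not tell whether these mice are unusual. Progeny 7 stood apart at -1.33 on chromosome 11 (55913468 to 55916508) and at -1.22 on chromosome 14 (114019472 to 114023022). Progeny 2 stood apart at -0.699 on chromosome 13 (from 112668288), and progeny 5 at 0.749 on chromosome 8 (from 119465394). With normexp correction the chromosome 13 value was -0.057, and with dim probes left out it was -0.19. Without the most extreme spot the 4 values were, in that order, -0.14, -0.12, -0.29 and 0.26.

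The father's columns of the value table entered only the value table alternative, and they do not follow the father's scanner files. Only 8 of the father's 217 regions reached 0.25 in the same direction there, while the 3 that met the stricter requirement all did. The father's columns gave 0.55 at the chromosome 4 gain and -0.90 at the chromosome 19 loss, beside 0.55 and -0.79 in the scanner files, with medians of 0.012 for X and -0.028 for Y. Among the 9 mice only the father has such values at all of these, but a mouse outside the family was not tested, and the origin of the columns is not known.

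The loss on chromosome 14 (53430657 to 54252014) was deeper in the parents than in the progeny. If the value table columns under the father's label are of the father, they argue against a cause in the father's generation, since they differed from the scanner files by 0.23 and gave -0.26, the value of the progeny mean. Under that condition an effect of the array batch that the parents shared stays a hypothesis. It would have to act on some loci only. The father's scanner files and value table columns gave 0.55 and 0.55 at the chromosome 4 gain, and -0.79 and -0.90 at the chromosome 19 loss. At the 5-probe chromosome 14 locus (from 52007419) they differed, at -0.13 and 0.17. A difference between DNA preparations was not tested and cannot be told apart from batch. For the mother there was no other set of hybridisations beside the -0.53 of the scanner files, so batch and generation cannot be told apart there. Which DNA preparation was used for either set is not given in the sources used here.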

How the results depend on the processing

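The stricter requirement and the 33 settings tried beside it were chosen after the data were seen; the other alternatives were planned. The counts of calls depended on most settings. From 1555 regions, 1380 loci and 744 progeny calls absent in the parents, a score of at least 5 gave 4879, 4199 and 2341, and of at least 8 gave 246, 186 and 97. With 5 or more probes they were 657, 565 and 327, and with a mean of at least 0.5 they were 820, 720 and 313. Normexp correction gave 313, 224 and 93, leaving out dim probes 475, 395 and 147, and the stricter requirement 33, 9 and 4. The arrays with the mouse in Cy3 alone gave 2528 regions and 2315 loci. The other planned settings stayed within 1.5 times of each count. Sign-turned regions fell from 1976 to 565 with the dye effect left in, to 122 with normexp correction and to 684 for a mean of at least 0.5, below the calls in each. Fewer calls follow from stricter thresholds by construction. With the dye effect left in, the sign-turned profiles hold that effect, so their count does not estimate noise alone. For the background settings the cause was not tested.

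Of the 33 tried settings, 31 gave fewer sign-turned than called regions, and 9 gave under 10% of them. These include settings with the dye effect left in, whose sign-turned counts hold that effect. Of called regions, normexp correction gave 102 and 64 at a score of 8 with 3 and 5 probes, 56 at 9 with 5 probes and 65 at 10 with 3. With the dye effect left in, it gave 308 at a score of 6 and then, in that order, 102, 66, 56 and 67. Leaving out dim probes likewise gave 116, 65, 47 and 57, and with the dye effect left in 460, 110, 65, 47 and 55. Processed signals with 5 probes gave 53 and, with the dye effect left in, 54 at a score of 9, then 43 at 10, and 46 at 8 with 10 probes. Adding 4 limits on the median probe, the highest 0.5, gave 1023, 485, 245 and 82 at a score of 6, and 161, 87, 54 and 32 at 8. At a score of 9 the 3 limits not taken up gave 44, 23 and 21. Progeny calls absent in the parents were then 7 against 5 sign-turned at the lowest limit, 2 against 0 at 0.35 and 0 against 0 at 0.5, so the 4 calls given in the report rest on the limit chosen.

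Windows shared by the progeny numbered 13, and 28 without a size limit, 7 at 0.5, 31 with 5 probes and 7 with 20 probes; leaving out 1 of the progeny gave 13 to 14. A scan batch block could not be fitted to the progeny alone. Windows differing between progeny and parents numbered 29, and 3218 without a size limit, 0 at 0.5 (limma; 20692 at an unadjusted p under 0.05), 1284 with 5 probes, 2 with 20 probes, 6 with normexp correction and 0 with the value table. Leaving out 1 mouse gave 25 to 777: 777 without the father, 100 without the mother, where the lone parent is assumed to vary like the progeny, and 44 without progeny 5. With scan batch as a random block there were 41, at an estimated correlation of -0.5903, which is not a usable estimate of a batch effect. The cause of these changes was not tested.

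The share of parental loci carried by the progeny was 2.5% to 15.4% under the planned settings and 6.5% to 9.5% without 1 of the progeny, and was 64.3% under the stricter requirement, on 2 loci. The difference in regions per mouse was -35.86 for a size of at least 0.5, and -31.43 to 146.57 without 1 mouse (-31.43 without the mother and 146.57 without the father). Normexp correction moved the X value of the father to 0.048, that of the mother to 0.503 and the mother's Y value to -0.286. Of the values of single loci, 127 stayed within their error, 72 moved and 4 changed sign: with the value table the father's -0.081 and -0.153 on chromosome 1 (from 96920897 and 178989562) and 0.065 on chromosome 13 (from 32895305), which do not follow the scanner files there, and 0.019 in progeny 3 on chromosome 2 (from 87491099) with normexp correction.

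No paired analysis was possible, because all the progeny share the same father and mother and the replicate numbers do not match mice between groups. The gene list tests and their alternatives were not run, for want of gene names on the build of the arrays. Short gains were harder to call in the parents than in the progeny. Of simulated gains of 3 probes 37.5% were recovered in the parents and 92.1% in the progeny, and of losses 100% in both.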

Other observations

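The tests in this part were all chosen after the results were seen. The chromosome 8 gain of 128.2 kb followed the same mice as the short losses of progeny 4 to 7: it was 0.24 in the mother and 0.25 to 0.30 in these progeny, and 0.05 or less in the father and the others. So did the 11-probe loss on chromosome 14 (from 61798066), at -0.16 in the mother and -0.44 to -0.19 in these progeny. In the father and the others it was between -0.01 and 0.03.

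A hypothesis for the 17 short losses carried by progeny 4, 5, 6 and 7 is that their probes also bind sequence of a sex chromosome, since these progeny have X medians of 0.89 to 0.99 and Y medians of -2.37 to -1.56. The mother, labelled female, carried 11 of the 17 and the father, labelled male, 1, which is consistent with that hypothesis. A separate inherited allele at each locus is argued against by 17 of 18 loci falling on the same one of 35 possible sets of 4 progeny. Scan day as the only cause is argued against by the parents, which shared a scan day. The mother lay further in the direction of the loss at 16 of 17 loci, by a median of 0.36 (exact two-sided sign test, p = 0.000275). That test counts the loci as independent, although they come from 1 mother and 1 father and may share a cause. Its p-value is therefore not a measure over mice. Among the progeny the split follows scan order, as mice 1 to 3 were scanned before mice 4 to 7. At 3 of the loci neither parent differed, and the probe sequences were not searched in a genome, so the hypothesis of sex chromosome sequence stays open.

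The levels of the chromosome 4 gain may reflect 3 copies in some mice and 4 in others against 2 in the reference. Each of the 9 mice lay within 0.09 of the log2 ratio for 3 or 4 copies. Scan day is argued against by progeny 6 and 7, which were scanned on the same day and differed by 0.37. Copy number was not measured by another method here, and no explanation from the groups of the design was tested.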
